A study of Oncorhynchus mykiss with 15 samples.

How the data were processed

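Liver RNA from rainbow trout (Oncorhynchus mykiss) was sequenced in 15 libraries of 5 groups, labelled N, H3h, H12h, H24h and R3h, with 3 libraries in each. The series describes its design as a study of hypoxia of different durations. The labels do not spell out the letters N, H and R, so the groups keep their code names here. The fish were 150 days old, and the livers were frozen in liquid nitrogen before total RNA was taken up in Trizol. Nothing in the labels says that the 3 libraries of a group come from separate fish, so p-values measure the spread between samples.

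The table deposited by the authors holds raw counts per gene, per the file headers, for 34965 genes in every library. The same deposited table gives FPKM (fragments scaled by gene length and library size) computed by the authors. The length implied by count and FPKM was the same for a gene across libraries, with a median coefficient of variation of 0.38%, so both kinds of column describe the same data. Per the submitters' processing notes, TopHat2 2.1.1 and Bowtie2 2.2.8 were used. The genome build, the annotation and the counting tool are not given in the sources used here, and coordinates below are those of the deposited table. Gene identifiers were looked up in a RefSeq table of assembly USDA_OmykA_1.1, which held 31271 of them, and no coordinates were taken from it. Symbols and product names are those the table assigns, often by similarity to other species, and 29141 genes carry one. The trout genome holds many duplicated genes, and near-identical copies can share reads, so values of single copies are less certain than those of a family.

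Before the data were examined, the comparisons, the tests, the 39 gene lists, the rule for naming genes and most alternatives were fixed. The design assumed FPKM values and limma, and provided for edgeR if counts were found. Counts were found, so edgeR's quasi-likelihood test was used, with trimmed-mean (TMM) scaling and all 15 libraries in a single fit of 5 group means. Genes with a mean FPKM of at least 0.5 over the libraries were tested, 17500 in all. They held at least 99.0% of the counts of every library. P-values were two-sided and adjusted by Benjamini-Hochberg within a comparison, and an adjusted p under 0.05 counted as a call, with no fold minimum. Fold changes are given as log2 from the fitted model. The standard error (SE) beside them is the absolute log2 fold change divided by the square root of the test's F statistic. The model does not give it directly, so it is an approximation. Levels are given as mean FPKM ± SD over the 3 libraries of a group. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

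Lists were tested with camera at a preset inter-gene correlation of 0.01, which compares the mean test statistic of a list's members with that of all other genes. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list move, on balance, one way, and compares them with no other genes. List p-values were adjusted over the 36 lists with at least 4 tested members. The lists of exocrine pancreas (3 tested members), intestine (3) and skeletal muscle (1) were too short to test. For every list, the number of called members is also given adjusted over the list alone. With an estimated correlation, no list passed in any of the 5 comparisons, so every camera call below is lost under that setting.

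Genes were named by a rule. From each comparison came the 6 largest positive and the 6 largest negative changes among called genes with a name, a mean FPKM of at least 5 in the higher group and groups that did not overlap. From each list came the 4 members with the smallest adjusted p, or the 2 with the smallest p where none passed. The most expressed copies of hif1a, egln3, vegfa, igfbp1, pck1, pdk2, ddit4, hspa5, per1, fkbp5 and hba were always included, and ldha had no match. Genes outside the rule are said to have been chosen after their values were seen. Some genes that the rule picks are not used here. Where a list failed every test its members are given only if they were called.

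The procedure was tested on simulated counts with the means, library sizes and dispersions of the data, in which 200 of 17500 genes were changed in H12h. EdgeR recovered 1.5% of genes changed 2-fold, 28.4% of those changed 4-fold and 71.2% of those changed 8-fold, and 4.3% of its calls were false. DESeq2 recovered 6%, 47.8% and 87.9%, with 27.7% false calls. Limma on log2(FPKM + 1) recovered 1.5%, 22.4% and 66.7%, with 4.8% false calls. Of 200 unchanged lists, camera with the preset correlation gave 4 with p below 0.05, camera with an estimated correlation 2 and fry 13. Genes were simulated independently of each other, so these rates say nothing about lists of correlated genes, and the correlation estimated in the real lists reached 0.73.

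Total counts ranged from 45.4 M in N replicate 1 to 70.4 M in H3h replicate 3. The number of genes with at least 10 counts ranged from 21443 in R3h replicate 3 to 26212 in N replicate 3. Over the tested genes as a whole, precision was set less by counting than by the spread between libraries, with a common biological coefficient of variation of 49.1%. Alternatives covered the filter, the scaling (median-of-ratios, FPKM and TPM), the pseudocount, a replicate block, robust dispersion, library weights, a fit of only the groups compared, DESeq2, a 2-fold minimum and the omission of each library. Limma on log2(FPKM + 1), limma-voom without weights, the omission of R3h replicate 3 from comparisons about other groups, leave-outs for the lists, the list tests between H times and the KEGG pathways were added after the data had been seen.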

Results

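Liver transcripts of 150-day-old rainbow trout were counted in 15 libraries, 3 each of the groups labelled N, H3h, H12h, H24h and R3h. The series speaks of hypoxia of different durations. The H labels carry 3, 12 and 24 h and the R label 3 h, while N carries no time. The labels give no N group matched to each time. Effects of the H or R condition therefore cannot be told apart from those of elapsed time or time of day. Total counts, in mega-counts (M), were 45.4, 59.1 and 63.1 M in N and 65.3, 53.5 and 70.4 M in H3h. They were 60.5, 46.7 and 65.5 M in H12h, 56.6, 65.4 and 59.2 M in H24h and 65.9, 62.6 and 54.0 M in R3h. Log2 fold changes are given ± SE and FPKM as mean ± SD, with n = 3 libraries per group.

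Marker transcripts of 8 cell types, red blood cells among them, were compared between groups. The mean log2(FPKM + 1) of 27 erythrocyte markers, 22 of them globins, was 3.18 ± 0.482 in N, 3.10 ± 0.702 in H3h, 3.75 ± 0.683 in H12h, 4.69 ± 0.735 in H24h and 4.15 ± 0.898 in R3h. The difference of 1.51 between H24h and N had an exact two-sided permutation p of 0.1, the smallest that 3 libraries against 3 allow. Hepatocyte markers such as albumin and transthyretin averaged 8.25 ± 0.50 in H24h and 7.57 ± 0.459 in N (difference 0.679, exact permutation p = 0.3). Cholangiocyte markers, of the bile duct lining, averaged 2.55 ± 0.14 in N, 2.03 ± 0.15 in H12h and 2.18 ± 0.177 in R3h. Their differences from N of -0.525 and -0.368 each had an exact permutation p of 0.1. Besides these and the erythrocyte markers in H24h, no difference reached that p in the 5 comparisons. On the same log2(FPKM + 1) scale the median of all genes was -0.355 in H12h and -0.286 in R3h against N. Much of the cholangiocyte difference was thus common to all genes. By edgeR the medians of that list were -0.29 and -0.26, and it passed camera's test in neither comparison. R3h replicate 3 stood apart from the other libraries. Its mean correlation with the other R3h libraries was 0.733, it had the fewest genes with at least 10 counts (21443), and its 10 most abundant genes took 32.3% of the counts. The median SD within a group was 0.696 (log2 CPM) in R3h and 0.354 to 0.403 in the other groups. N and H12h were not uniform either. On the first and second principal components N replicate 2 lay at -15.8 and -37.3, near H12h replicate 1 (-27.3 and -22.8). N replicates 1 and 3 lay at -79.7 and 67.7 and at -50.9 and 31.5. On the third component H12h replicate 3 lay at 10.8, and H12h replicates 1 and 2 at -80.8 and -118.

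**Figure D1:**
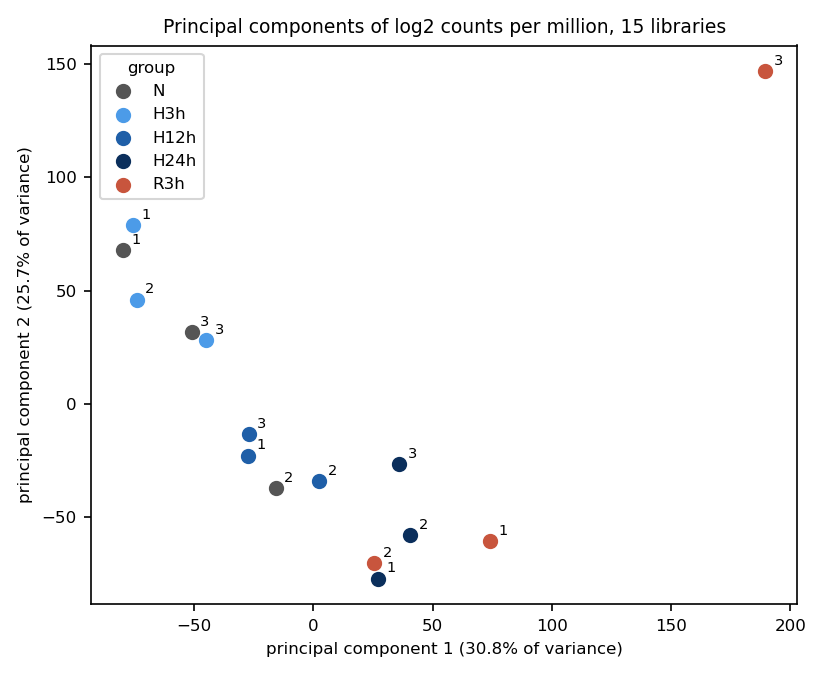
First against second principal component of the 15 libraries, from log2 CPM of the tested genes; each point is a library and its colour the group. The components hold 30.8% and 25.7% of the variance, and R3h replicate 3 lies alone at 189.5 and 146.9.

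Across the 5 groups, Egln3 and ddit4 of the hypoxia response had their highest means in H12h. Egln3 (110505778), a prolyl hydroxylase that marks the hypoxia-inducible factor (HIF) for destruction and is itself induced by it, averaged 0.243 ± 0.0473 FPKM in N, 3.11 ± 2.66 in H3h, 13.3 ± 3.76 in H12h, 0.983 ± 0.505 in H24h and 10.1 ± 9.68 in R3h. Ddit4 (110531799), an inhibitor of mTOR signalling, averaged 1.44 ± 0.439, 30 ± 13.6, 257 ± 248, 3.01 ± 1.93 and 8.58 ± 7.32 FPKM in the same order. The quasi-likelihood F-test of edgeR called 1267 of 17500 genes at an adjusted p under 0.05, and 5075 had an unadjusted p under 0.05. The count depended on single libraries. It was 655 without N replicate 1 and 199 without N replicate 3. It was 210, 285 and 483 without H3h replicates 1, 2 and 3, and 286 and 487 without H12h replicates 1 and 2. It was 681, 287 and 430 without H24h replicates 1, 2 and 3, and 502, 2117 and 2675 without R3h replicates 1, 2 and 3.

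**Figure D2:**
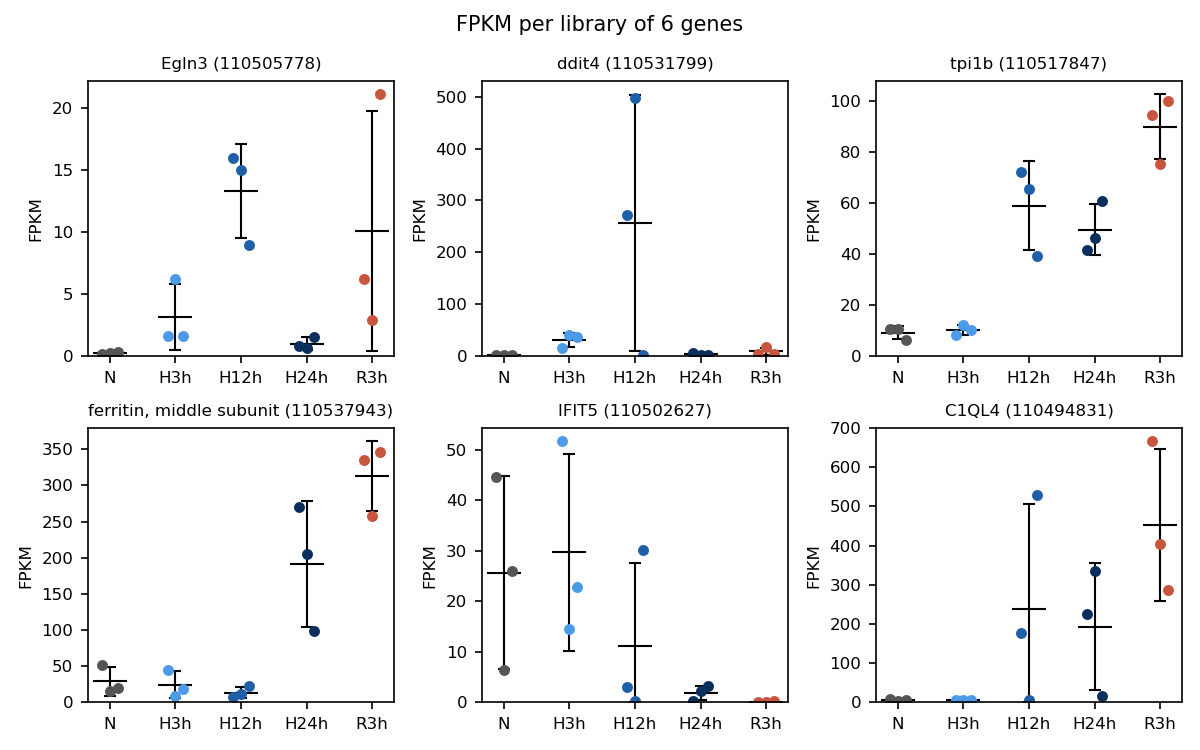
FPKM of 6 genes in each library (vertical axis, linear, from 0; horizontal axis, the 5 groups); points are libraries, the bar is the group mean and the error bar the SD of 3 libraries, not drawn below 0. Egln3 and ddit4 have their highest means in H12h, tpi1b and the ferritin gene 110537943 in R3h, IFIT5 is near 0 in R3h, and C1QL4 is 287.51 FPKM or more in every R3h library.

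The comparison of H3h with N asked what the shortest H time changed. No gene passed the test, and genes of the hypoxia, stress-hormone and immediate-early responses are given first because their lists passed. Egln3 (110505778) differed by 3.64 ± 0.78, from 0.243 ± 0.0473 to 3.11 ± 2.66 FPKM, and ddit4 by 4.35 ± 1.27. Tsc22d3, a glucocorticoid-induced leucine zipper protein, stood at 29 ± 9.44 against 5.26 ± 1.15 FPKM (2.45 ± 0.55). DUSP1, a phosphatase that ends MAP kinase signals, stood at 45.1 ± 24 against 5.91 ± 7.82 FPKM (2.98 ± 1.10), and Nr0b2 (110496393), a repressor of bile acid synthesis, at 0.0933 ± 0.0902 against 14 ± 23.5 FPKM (-7.46 ± 1.71). The adjusted p of each was 1. Among the other genes always followed, IGFBP1 differed by 2.01 ± 1.28, PCK1 by 1.51 ± 1.13, hspa5 by 0.81 ± 0.61, FKBP5 by 0.91 ± 0.65 and Per1 by 0.76 ± 0.46. Vegfaa (110529696) differed by 0.42 ± 0.49, Egln3 (110497687) by 0.71 ± 0.74, Pdk2 by 0.32 ± 0.71, hif1a by 0.19 ± 0.30 and hba4 by -0.05 ± 0.64. EdgeR called 0 of 17500 genes, with 383 at an unadjusted p under 0.05, and 8.8% of genes had groups that did not overlap, where chance gives 10%. DESeq2 called 14. Limma called 1 on log2(FPKM + 1), namely COL6A1 (110535491), a collagen chain at 0 FPKM in every H3h library and 3.47 ± 2.14 in N. Limma-voom with library weights called 4, G0s2, FSTL3, Tsc22d3 and BMP5, chosen after their values were seen as was COL6A1.

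Lists passed at H3h with camera's preset correlation although no gene did. Immediate-early genes rose (46 of 53 members positive, median 0.89, camera adjusted p = 1.8e-14, adjusted p = 0.52 with an estimated correlation), with DUSP1 and ier2 (2.25 ± 0.86) in front. Glucocorticoid-responsive genes rose (17 of 19 positive, median 0.91, adjusted p = 3.2e-13, adjusted p = 0.41 with an estimated correlation), with Tsc22d3 passing when adjusted over the list alone and Klf9 at 1.83 ± 0.83. HIF targets rose by a median of 0.17 (37 of 57 positive; 4 higher and 1 lower when adjusted over the list alone), with ankrd37 at 2.1 ± 0.46 beside Egln3 (adjusted p = 7.5e-05, adjusted p = 0.56 with an estimated correlation). Xenobiotic and bile acid genes fell (30 of 35 negative, median -0.42, 2 lower when adjusted over the list alone, adjusted p = 2.4e-07, adjusted p = 0.52 with an estimated correlation), led by both Nr0b2 copies (-7.46 ± 1.71 and -3.45 ± 0.92). These 4 calls held without each of the 6 libraries in turn. Hepatocyte markers fell (26 of 28 negative, median -0.51, adjusted p = 0.00011, adjusted p = 0.57 with an estimated correlation), with the alb1 copies 110531470 and 110531464 at -6.01 ± 1.87 and -1.74 ± 0.89. That call was lost without N replicate 2 (adjusted p = 0.39).

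Each of the remaining 12 list calls at H3h was lost when a single library was left out. Medians were positive for apoptosis and p53 genes (0.34, adjusted p = 0.0078; sesn1 -2.16 ± 0.67, Bcl2l11 1.72 ± 0.73), heat shock proteins (0.24, adjusted p = 0.008; the hsp30 copies 2.36 ± 1.20 and 2.63 ± 1.48) and clock genes (0.32, adjusted p = 0.011; TEF 1.37 ± 0.47, CRY1 1.41 ± 0.54). They were also positive for the unfolded protein response (0.19, adjusted p = 0.012; SDF2L1 0.61 ± 0.35, PPP1R15A 0.83 ± 0.53), inflammatory genes (0.25, adjusted p = 0.014; tnf 2.89 ± 1.35, Irf1 0.67 ± 0.38), ribosome biogenesis (0.14, adjusted p = 0.037; the DDX21 copies -0.47 ± 0.37 and 0.36 ± 0.33) and lymphocyte markers (0.20, adjusted p = 0.039; IL7R 1.11 ± 0.50, CCR7 0.77 ± 0.54). They were negative for fatty acid oxidation (-0.21, adjusted p = 0.012; the Acaa2 copies -1.33 ± 0.56 and -0.85 ± 0.44), macrophage markers (-0.57, adjusted p = 0.012; CD74 -1.23 ± 0.68, c1qa -1.46 ± 0.81) and vitellogenesis (-1.05, adjusted p = 0.019; esr1 -1.11 ± 0.60, vtg1 -4.54 ± 2.74). They were also negative for ribosomal proteins (-0.14, adjusted p = 0.02; RPS27 -0.74 ± 0.41, rps3 0.53 ± 0.31) and glycogen metabolism (-0.31, adjusted p = 0.039; ppp1r3b -3.28 ± 1.27). With an estimated correlation the adjusted p of these lists lay between 0.52 and 0.81. Without H3h replicate 1 all 12 failed except the unfolded protein response, which failed without N replicate 1 (adjusted p = 0.14). It also failed without H3h replicate 2 (0.82). Without N replicate 2, 9 of the 12 failed, among them fatty acid oxidation (0.81) and vitellogenesis (0.57). The number of lists that passed was 10 without H3h replicate 1.

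At H12h the hypoxia-responsive programme was high. Egln3 (110505778; chromosome 25, 69369452 to 69384060, build not given in the sources used here) rose from 0.243 ± 0.0473 to 13.3 ± 3.76 FPKM (6.26 ± 0.88, adjusted p = 0.018). Hif1an, the asparaginyl hydroxylase that restrains HIF activity, rose from 3.55 ± 1.12 to 44.2 ± 14.1 FPKM (4.12 ± 0.68, adjusted p = 0.026). Tpi1b (110517847; chromosome 3, 33990921 to 33995689), a glycolytic isomerase, rose from 9.10 ± 2.55 to 59 ± 17.5 FPKM (3.22 ± 0.43, adjusted p = 0.018). Ddit4 (chromosome 1, 83843012 to 83844911) rose by 8.09 ± 1.5 (adjusted p = 0.046), but its libraries held 271.08, 496.62 and 1.96 FPKM, and H12h replicate 3 was near N. CYP24A1, which inactivates vitamin D, rose from 19.8 ± 10.2 to 399 ± 247 FPKM (4.94 ± 0.77, adjusted p = 0.022). Ero1a, an oxidase that forms disulfide bonds in the endoplasmic reticulum, rose by 5.01 ± 0.73 (adjusted p = 0.019) and ANKRD10 by 4.15 ± 0.69 (adjusted p = 0.027). The 5 genes that fell were TUBA1C (-1.75 ± 0.32, 35.8 ± 5.94 to 7.47 ± 1.85 FPKM), NFE2L2, the master regulator of antioxidant genes (-3.15 ± 0.53), and, outside the naming rule and chosen after their values were seen, ACSL1 (-3.81 ± 0.67), ATP8B2 (-2.23 ± 0.33) and taf2 (-1.64 ± 0.29). Their adjusted p lay between 0.019 and 0.046.

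In the test by edgeR, 39 genes passed at H12h, 34 higher and 5 lower, all by at least 2-fold; 2506 had an unadjusted p under 0.05 and 24.5% had groups that did not overlap, where chance gives 10%. The count was 0 without N replicate 1, N replicate 3 or H12h replicate 2, 3 without N replicate 2 (ankrd37, tpi1b and apln, the last chosen after its values were seen) and 7 without H12h replicate 1. It was 546 without H12h replicate 3 and 306 without R3h replicate 3. Limma, which changes both the scaling and the test, gave 17 higher and 7 lower on log2(FPKM + 1) and 24 higher and 8 lower on log2(TPM + 1). The median of all genes was -0.355 and -0.367 there and -0.07 in the fit by edgeR, so changes are relative to the typical gene.

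HIF targets rose as a group at H12h (49 of 57 positive, median 1.65, camera adjusted p = 5.6e-21, adjusted p = 0.13 with an estimated correlation, fry adjusted p = 0.019). Of its members 7 were called over all genes and 27 when adjusted over the list alone. Besides Egln3, ero1a and ddit4 these included ankrd37 (3.85 ± 0.49, adjusted p = 0.018), P4HA1, a collagen prolyl hydroxylase (2.14 ± 0.723 against 0.0233 ± 0.0208 FPKM, adjusted p = 0.019), and both Egln1 copies (2.32 ± 0.39 and 1.92 ± 0.30). Vegfaa, the angiogenic growth factor, stood at 21.1 ± 14.6 against 5.04 ± 1.29 FPKM (2.65 ± 0.52, adjusted p = 0.06) and IGFBP1 at 199 ± 220 against 7.46 ± 3.01 (5.41 ± 1.49, adjusted p = 0.13), neither called. Hif1a itself, regulated mainly as a protein, differed by -0.62 ± 0.30 (adjusted p = 0.36), Egln3 (110497687) by 3.19 ± 0.79 (0.095) and Pdk2 by 2.09 ± 0.74 (0.22). Glucocorticoid-responsive genes rose (16 of 19 positive, median 1.97, adjusted p = 2.6e-09, adjusted p = 0.40 with an estimated correlation), with Tsc22d3 called (3.46 ± 0.58, adjusted p = 0.027) and 11 higher and 1 lower when adjusted over the list alone. FKBP5 differed by 1.39 ± 0.65 (0.35), PCK1 by 2.97 ± 1.19 (0.28), hspa5 by 0.50 ± 0.60 (0.75) and Per1 by -0.02 ± 0.46 (0.99). Immediate-early genes rose (44 of 53 positive, median 0.97, 9 when adjusted over the list alone, adjusted p = 2e-07, adjusted p = 0.51 with an estimated correlation), with BTG1 at 3.40 ± 0.72 and FOSB at 10.7 ± 9.42 against 0.02 ± 0.0173 FPKM, neither called.

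Protein synthesis and breakdown genes parted at H12h. Ribosomal proteins rose (172 of 185 positive, median 0.56, adjusted p = 7e-13; rps23 1.77 ± 0.37, rpl27 1.03 ± 0.26, neither called). Proteasome subunits fell (87 of 94 negative, median -0.85, adjusted p = 1.7e-12; PSMC1 -1.48 ± 0.36, Psmd1 -1.73 ± 0.43, neither called). With an estimated correlation both had an adjusted p = 0.51. Ribosome biogenesis genes fell (43 of 48 negative, median -0.56, adjusted p = 0.00017, adjusted p = 0.61 with an estimated correlation; DDX21 1.08 ± 0.37, bop1 -0.94 ± 0.38). Other lists were higher, namely acute-phase proteins (median 0.86, adjusted p = 8.9e-09; CRP 1.42 ± 0.32), hepatocyte markers (0.67, adjusted p = 0.0011; Apoh 1.01 ± 0.36, apoa2 1.18 ± 0.49), gluconeogenesis (0.80, adjusted p = 0.0011; foxo1a 2.36 ± 0.50, G6PC 2.70 ± 0.68) and vitellogenesis (0.44, adjusted p = 0.014; the ZP4 copies 3.06 ± 0.63 and 1.29 ± 0.47). Each had an adjusted p = 0.51 with an estimated correlation. The G6PC copies did not move alike by mean FPKM in H12h against N. Copies 110499065 (193 ± 98.2 against 82.1 ± 26.1) and 110491474 (171 ± 111 against 40.3 ± 13.6) were higher. Copy 110486384 was lower (1.56 ± 1.33 against 19.2 ± 18.5). Amino acid catabolism genes rose (36 of 47 positive, median 0.58, adjusted p = 6e-06, adjusted p = 0.26 with an estimated correlation, fry adjusted p = 0.035; ARG2 3.42 ± 0.90). Heat shock proteins rose (median 0.28, 10 higher and 1 lower when adjusted over the list alone, adjusted p = 0.0011), with hsp30 called at 3.93 ± 2.58 against 0.0367 ± 0.0351 FPKM. Glycolysis genes rose (0.43, 5 higher and 1 lower when adjusted over the list alone; adjusted p = 0.0064), with tpi1b as the called member. Both had an adjusted p = 0.51 with an estimated correlation.

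Erythrocyte markers rose with these lists (26 of 27 positive, median 1.20, adjusted p = 2e-07; hbb 1.52 ± 0.57, hba4 110486353 2.44 ± 0.94, hba4 100136296 1.20 ± 0.65). Other shifts that passed at H12h were those of autophagy (0.33, adjusted p = 0.0025; GABARAPL1 1.60 ± 0.33, Ulk1 2.59 ± 0.63), oxidative phosphorylation (0.25, adjusted p = 0.0011; COX5B 1.26 ± 0.31, ATP5E 1.58 ± 0.44) and stellate cell markers (0.41, adjusted p = 0.0041; the TAGLN copies 1.54 ± 0.48 and 0.64 ± 0.34). So were apoptosis (0.18, adjusted p = 0.036; GADD45G 4.90 ± 1.14, GADD45A -3.59 ± 0.99), endothelium (0.02, adjusted p = 0.038; CDH5 1.16 ± 0.24, kdr 1.38 ± 0.45) and cholesterol synthesis (0.21, adjusted p = 0.04; insig1 2.16 ± 0.67). With an estimated correlation their adjusted p lay between 0.51 and 0.70. The medians of autophagy, oxidative phosphorylation, apoptosis, endothelium and heat shock proteins turned negative on the FPKM and TPM scales, and that of glycolysis was -0.03 on the FPKM scale. On these scales the median of ribosomal proteins was 0.05 and 0.11, that of amino acid catabolism 0.1 and 0.16 and that of cholesterol synthesis 0 and 0.07. The median of HIF targets was 0.62 and 0.76 there, and that of acute-phase proteins 0.31 and 0.41. Gluconeogenesis stood at 0.26 and 0.33 and erythrocyte markers at 0.52 and 0.59. With a pseudocount of 0.1 the calls of oxidative phosphorylation (adjusted p = 0.071) and endothelium (0.083) were lost. Calls lost without a library were oxidative phosphorylation without H12h replicate 2 (adjusted p = 0.12), heat shock and apoptosis without N replicate 2 (0.056 and 0.073), apoptosis without H12h replicate 2 (0.16), stellate markers without N replicate 1 (0.16) and vitellogenesis without N replicate 3 (0.17). Endothelium was lost without N replicates 1 and 3 (0.1 and 0.082) and H12h replicates 1 and 3 (0.11 and 0.18), and cholesterol synthesis without H12h replicates 1 and 2 (0.13 each) and N replicate 3 (0.69).

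Ferritin genes, which store iron, were among those called at H24h. Of 21 ferritin genes 4 rose, all middle subunits: 100136293 (18.5 ± 9.33 to 109 ± 47.1 FPKM, 2.93 ± 0.52), 110538928 (121 ± 42.6 to 505 ± 91.6, 2.40 ± 0.42), 110537944 (101 ± 4.18 to 421 ± 107, 2.37 ± 0.33) and, outside the naming rule, 100136294 (1.98 ± 0.37). Their adjusted p lay between 0.028 and 0.047. The family had a median of 1.71 with 20 of 21 positive, although frih was lower in H24h by mean FPKM (778 against 836), and tandem copies may share reads. Erythrocyte markers were higher in the same comparison (median 2.15, 27 of 27 positive). Bach1, a haem-sensing repressor of ferritin genes, fell from 4.51 ± 2.32 to 0.703 ± 0.155 FPKM (-2.32 ± 0.34, adjusted p = 0.028), chosen after its values were seen. Tpi1b rose by 2.73 ± 0.42 (adjusted p = 0.037), pno1, a ribosome assembly factor, by 2.39 ± 0.38 (0.039), bbip1 by 2.36 ± 0.35 (0.028) and cyp2k1, a fish cytochrome P450, from 36.2 ± 7.87 to 110 ± 13.6 FPKM (1.89 ± 0.32, 0.044). Lower genes were Ikbke, a kinase that triggers interferon production (11.9 ± 2.28 to 1.43 ± 0.372 FPKM, -2.65 ± 0.43, adjusted p = 0.039), the translation factor EIF4G1 (-2.44 ± 0.40), psmg2, a proteasome assembly chaperone (-2.07 ± 0.37), TAF15 (-1.97 ± 0.34), the alanyl-tRNA synthetase Aars (-1.70 ± 0.31) and KTN1 (-1.49 ± 0.27). Their adjusted p lay between 0.039 and 0.047.

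In the test by edgeR, 35 genes passed at H24h, 22 higher and 13 lower, all by at least 2-fold; 3442 had an unadjusted p under 0.05 and 32% had groups that did not overlap, where chance gives 10%. The count was 0 without N replicate 1, without N replicate 3 and without each H24h library, 181 without N replicate 2 and 683 without R3h replicate 3. Limma called 16 higher and 33 lower on log2(FPKM + 1), and 8 and 28 on log2(TPM + 1), where the median of all genes was -0.224 and -0.323, against -0.05 by edgeR. Of the genes always followed, Egln3 (110497687), ddit4, vegfaa 110529696, IGFBP1 and Pdk2 had smaller differences from N than at H12h. No gene was called in H24h against H12h. Another vegfaa copy, 100136118, averaged 5.01 ± 1.25 FPKM in H24h and 4.88 ± 1.62 in H12h. Egln3 (110497687) differed from N by 1.45 ± 0.75 (adjusted p = 0.30), ddit4 by 1.27 ± 1.13 (0.55), vegfaa 110529696 by 0.38 ± 0.49 (0.69), IGFBP1 by 3.64 ± 1.37 (0.18) and Pdk2 by 1.59 ± 0.73 (0.25). FKBP5 differed by -0.29 ± 0.64 (0.83), hspa5 by -0.98 ± 0.61 (0.39), Per1 by -0.52 ± 0.46 (0.55) and hif1a by -1.15 ± 0.30 (0.11). PCK1, of gluconeogenesis and glucocorticoid-induced, stood at 11.6 ± 3.68 against 104 ± 118 FPKM (-2.63 ± 1.18, 0.24).

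Erythrocyte markers rose in H24h (27 of 27 positive, median 2.15, 22 when adjusted over the list alone, adjusted p = 1.4e-15), with hbb at 24.7 ± 12.4 against 5.17 ± 1.58 FPKM, hba at 77.7 ± 27.7 against 16.6 ± 3.54 and hba4 (100136296) at 450 ± 253 against 112 ± 29.1, none called over all genes. Ribosomal proteins rose (169 of 185 positive, median 0.66, 12 when adjusted over the list alone, adjusted p = 1.4e-15; rpl27 1.22 ± 0.26), as did oxidative phosphorylation genes (123 of 164 positive, median 0.48, 7 when adjusted over the list alone, adjusted p = 3.7e-08; COX5B 1.59 ± 0.31, UQCR10 2.08 ± 0.46). Xenobiotic genes rose (median 0.68, cyp2k1 called, 5 when adjusted over the list alone, adjusted p = 9.9e-06) and so did hepatocyte markers (0.91; adjusted p = 0.00021), with fabp10a (110488894), the liver fatty acid carrier, at 285 ± 201 against 19.1 ± 12.8 FPKM (4.04 ± 0.76, adjusted p = 0.055) and its copy 110517089 at 2.43 ± 0.64. Each of these 5 lists had an adjusted p = 0.64 with an estimated correlation. The median implied length was 707 bases for ribosomal and oxidative phosphorylation genes and 2410 for all tested genes. Differences of H24h replicates 1, 2 and 3 from their group correlated with gene length (Spearman rho across genes 0.304, -0.259 and -0.183). Gene length as a cause of list shifts or gene calls at H12h and H24h was not tested. Other shifts upward passed for amino acid catabolism (0.54, adjusted p = 0.0023; ARG1 2.55 ± 0.58), antioxidant genes (0.43, adjusted p = 0.0082; SOD2 0.95 ± 0.29, prdx1 1.03 ± 0.34) and HIF targets (0.38, adjusted p = 0.013; P4HA1 0.38 ± 0.0985 against 0.0233 ± 0.0208 FPKM, vegfaa 100136118 1.17 ± 0.33). They also passed for glucocorticoid-responsive genes (0.38, adjusted p = 0.013; tat 1.96 ± 0.45, Tsc22d3 2.26 ± 0.55), fatty acid oxidation (0.45, adjusted p = 0.014; CPT1A 1.66 ± 0.44), stellate cell markers (0.53, adjusted p = 0.012; TAGLN 1.44 ± 0.48, ACTA2 -1.51 ± 0.55) and vitellogenesis (0.66, adjusted p = 0.014; vtg3 2.58 ± 1, ZP4 1.18 ± 0.47). With an estimated correlation their adjusted p was 0.64 to 0.67. On the TPM scale the medians of fatty acid oxidation and HIF targets were -0.02 and -0.01, and those of oxidative phosphorylation, amino acid catabolism, antioxidant and glucocorticoid-responsive genes 0.04, 0.08, 0.03 and 0.06. Ribosomal proteins had a median of 0.26 there, xenobiotic genes 0.35, hepatocyte markers 0.49 and erythrocyte markers 1.63.

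Lists of inflammatory, ribosome biogenesis, unfolded protein and proteasome genes fell in H24h. Inflammatory and interferon genes had 34 of 37 members negative (median -1.12, adjusted p = 8.8e-05, adjusted p = 0.64 with an estimated correlation), with IRF3, a transcription factor of interferon genes, at 4.82 ± 2.62 against 60 ± 18.8 FPKM (-3.34 ± 0.80, adjusted p = 0.096) and Irf1 at 1.23 ± 0.38. Neutrophil markers did not pass (median -0.30, adjusted p = 0.25, 5 of 16 lower when adjusted over the list alone). Among them MMP9 (110492670) stood at 0.563 ± 0.592 FPKM, while its N libraries held 192.78, 0.31 and 21.98, and MPO (110532736) at 4.88 ± 2.74 against 25.7 ± 23.2, neither called. Erythrocyte and hepatocyte markers were higher in the same libraries. Ribosome biogenesis genes fell (median -0.90, adjusted p = 7.7e-05, adjusted p = 0.64 with an estimated correlation; NOLC1 -1.52 ± 0.39, POLR1B -2.02 ± 0.59). The unfolded protein response fell (49 of 63 negative, median -0.62, adjusted p = 0.0019, adjusted p = 0.64 with an estimated correlation; CANX -1.42 ± 0.31, DDIT3 1.57 ± 0.49). Proteasome subunits fell (75 of 94 negative, median -0.46, 4 when adjusted over the list alone, adjusted p = 0.00026, adjusted p = 0.72 with an estimated correlation; Psmd1 -2.06 ± 0.44, PSMD2 -1.65 ± 0.38). The proteasome call was lost without H24h replicate 1 (0.16) and the glucocorticoid call without N replicate 2 (0.20). Fatty acid oxidation was lost without N replicate 3 (0.092) or H24h replicate 1 (0.059), stellate markers without N replicates 1 and 3 (0.15 and 0.06), and vitellogenesis without N replicate 3 (0.097), H24h replicate 1 (0.058) or H24h replicate 2 (0.056).

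**Figure D3:**
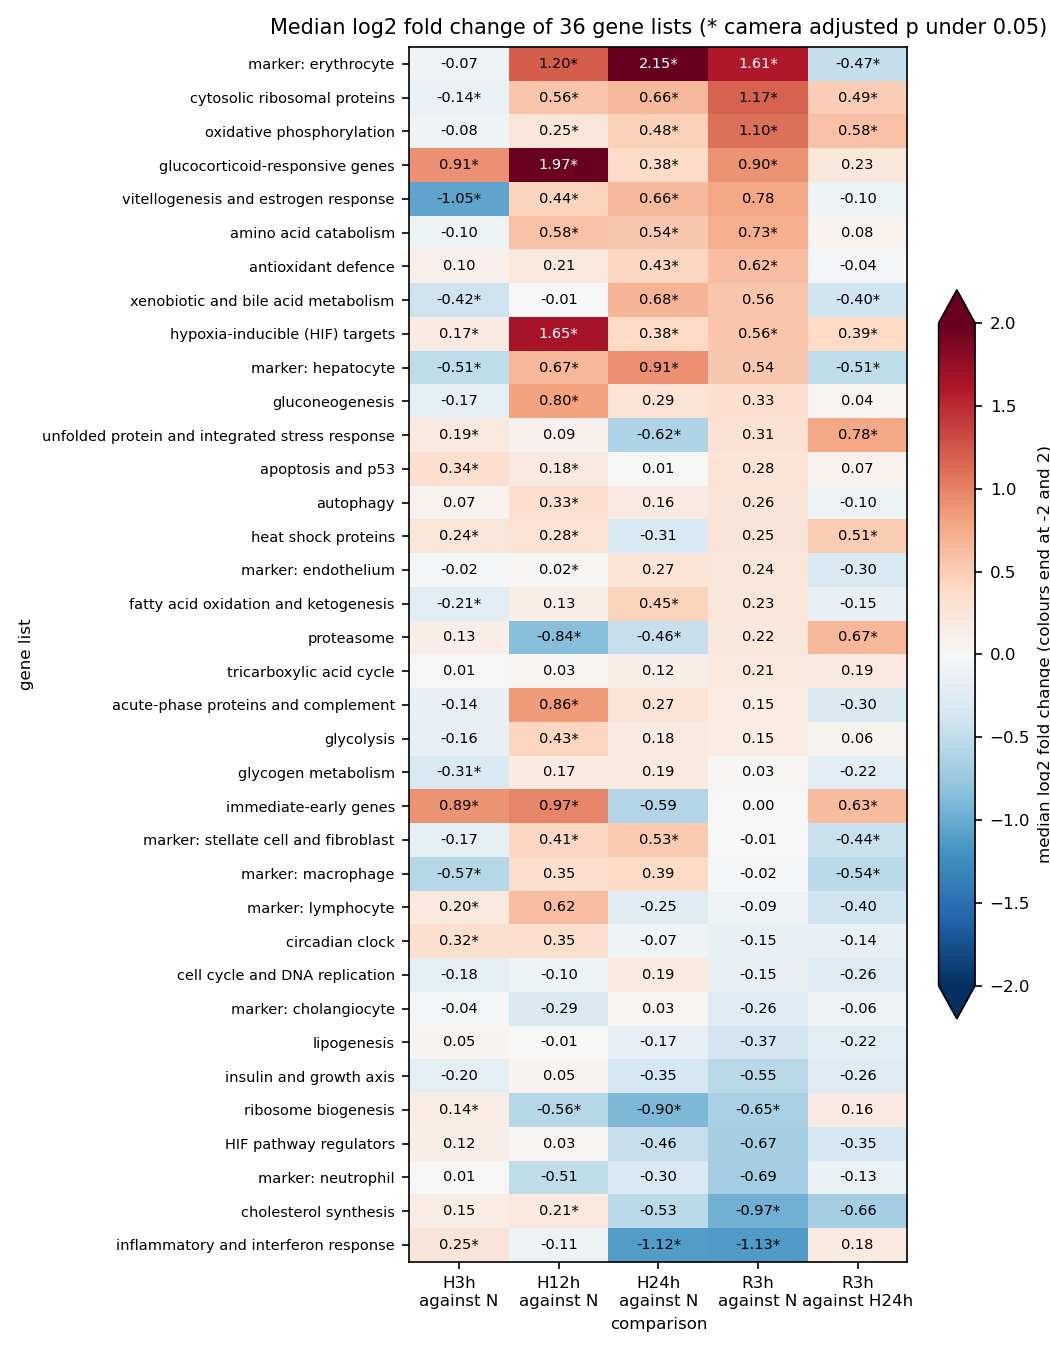
Median log2 fold change of each of the 36 tested gene lists (vertical axis) in 5 comparisons (horizontal axis); colours end at -2 and 2, and an asterisk marks a camera adjusted p under 0.05 with the preset correlation, which no list keeps with an estimated correlation. HIF targets are highest in H12h (1.65), erythrocyte markers in H24h (2.15) and ribosomal proteins in R3h (1.17), while inflammatory and interferon genes are negative in H24h (-1.12) and R3h (-1.13).

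R3h against N gave more called genes than the other pairwise comparisons in the fit of all libraries by edgeR, but not with library weights or in a fit of only the groups compared, which called 0. C1QL4 (110494831), a secreted C1q-family protein, rose from 6.80 ± 2.60 to 453 ± 194 FPKM (6.52 ± 1.35, adjusted p = 0.024), and Egln3 (110505778) to 10.1 ± 9.68 FPKM (5.69 ± 0.85, adjusted p = 0.011). The ferritin genes 110537943 (28.9 ± 19.7 to 313 ± 48.4 FPKM, 3.89 ± 0.64, adjusted p = 0.016) and 110537950 (3.79 ± 0.90, 0.033) rose with 11 other ferritin genes, 13 of 21 in all. The family's median was 2.17 and all 21 were positive, although by mean FPKM frih (804 against 836), 110537940 (6.18 against 7.31) and 110537949 (4.41 against 4.51) were lower. Erythrocyte markers were higher here too, with a median of 1.61. Tpi1b rose to 90 ± 12.8 FPKM (3.67 ± 0.44, adjusted p = 0.005) and miox, an inositol-degrading oxygenase, by 4.30 ± 0.86 (0.022). Of the genes that the rule names, those with the largest falls were IFIT5, from 25.7 ± 19.1 to 0.15 ± 0.141 FPKM (-6.86 ± 1.58, adjusted p = 0.031), Parp12 (-6.26 ± 0.89, 0.0094), GVINP1 from 52.3 ± 15.2 to 1.28 ± 0.633 FPKM (-4.91 ± 0.86, 0.018) and ERAP2, which trims peptides for antigen presentation (-5.26 ± 0.59, 0.005). Lgals3bpb (-5.15 ± 0.99, 0.02) and si:ch211-152f22.4 (-5.65 ± 1.14, 0.022) fell with them. All these genes had groups that did not overlap, R3h replicate 3 included.

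In the test by edgeR, 935 genes passed in R3h against N, 621 higher and 314 lower, 928 of them by at least 2-fold; 4649 had an unadjusted p under 0.05 and 27.9% had groups that did not overlap, where chance gives 10%. The count was 11 without N replicate 1, 7 without N replicate 3, 283 without R3h replicate 1 and 2452 without R3h replicate 2. Without R3h replicate 3 it was 1140, 621 higher and 519 lower. Limma gave another balance of directions, with 324 higher and 1566 lower on log2(FPKM + 1) and 269 and 1780 on log2(TPM + 1). The median of all genes was -0.286 and -0.400 there and -0.04 by edgeR, and scaling and test changed together.

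Genes of the ribosome and of mitochondrial respiration rose together in R3h. Of 185 ribosomal protein genes 57 were called, all higher (127 higher and 1 lower when adjusted over the list alone; 172 positive, median 1.17), and of 164 oxidative phosphorylation genes 58 were called, all higher (more when adjusted over the list alone, 150 positive, median 1.10). Camera gave adjusted p = 9.2e-27 and 4.5e-26; with an estimated correlation the adjusted p was 0.64 and 0.34, and by fry 0.039 and 0.015. Members were rps23 (2.27 ± 0.38, adjusted p = 0.016), rpl27 (191 ± 3.18 to 396 ± 31 FPKM, 1.42 ± 0.27, 0.019), rpl22 (2.13 ± 0.40, 0.02) and rps27 (2.06 ± 0.39, 0.02), and Atp5g3 (11.6 ± 3.11 to 36.7 ± 6.44 FPKM, 1.99 ± 0.34, 0.017), NDUFB5 (2.29 ± 0.39, 0.017), NDUFB4 (1.95 ± 0.35, 0.018) and ATP5E (2.48 ± 0.46, 0.018). R3h replicate 3 was the highest R3h library for these 8 genes, and without it the medians of the lists were 0.72 and 0.75. On the TPM scale their common median was 0.55, where that of all genes was -0.40. Without R3h replicate 3 these were 0.27 and -0.34. Mitochondrial enzymes outside the list were also called: SDHC (1.48 ± 0.26, adjusted p = 0.018), MDH2 (1.42 ± 0.32, 0.031) and sdhdb (1.06 ± 0.28, 0.044) of the tricarboxylic acid cycle, whose list did not pass (median 0.21, adjusted p = 0.22).

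HIF targets rose again in R3h (42 of 57 positive, median 0.56, 7 called, 11 higher and 1 lower when adjusted over the list alone, adjusted p = 9.6e-05, adjusted p = 0.64 with an estimated correlation, fry adjusted p = 0.068), with ankrd37 (3.22 ± 0.48, adjusted p = 0.011), EGLN1 (1.74 ± 0.30, 0.017) and P4HA1 (1.07 ± 0.822 against 0.0233 ± 0.0208 FPKM, 0.017) beside Egln3. Of the HIF regulators hif1an rose (2.82 ± 0.64, adjusted p = 0.031) and Epas1, which encodes HIF-2 alpha, fell from 33.8 ± 17 to 3.37 ± 2.97 FPKM (-2.92 ± 0.69, 0.033), and the list had a median of -0.67 (adjusted p = 0.073; fry adjusted p = 0.04). Inflammatory and interferon genes fell (34 of 37 negative, median -1.13, 3 called, 7 when adjusted over the list alone, adjusted p = 3.1e-05, adjusted p = 0.34 with an estimated correlation, fry adjusted p = 0.015). Amino acid catabolism genes rose (40 of 47 positive, median 0.73, adjusted p = 0.00022, adjusted p = 0.34 with an estimated correlation, fry adjusted p = 0.017), with 3 called, among them GOT1 (1.93 ± 0.35, 0.018). Antioxidant genes rose (median 0.62, adjusted p = 0.0034, adjusted p = 0.64 with an estimated correlation), with prdx1 (1.57 ± 0.35, 0.029) and PRDX5 (1.66 ± 0.39, 0.034) called. Erythrocyte markers rose (25 of 27 positive, median 1.61, adjusted p = 5.6e-07, adjusted p = 0.78 with an estimated correlation), with hbb1 (100136207) called (80.6 ± 70.3 against 14.9 ± 4.92 FPKM, 2.72 ± 0.74, adjusted p = 0.0499).

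On the TPM scale the medians of HIF targets, amino acid catabolism and antioxidant genes in R3h against N were 0.08, 0.17 and 0.06. Further list calls in R3h were glucocorticoid-responsive genes (median 0.90, adjusted p = 0.035; Tsc22d3 2.79 ± 0.56, 0.022, and tat 1.88 ± 0.45, 0.034), ribosome biogenesis (-0.65, adjusted p = 0.035; POLR1B -2.18 ± 0.59, 0.049) and cholesterol synthesis (-0.97, adjusted p = 0.039; FDPS -3.08 ± 1.08, insig1 110520389 0.67 ± 0.24, neither called). Each had an adjusted p = 0.79 with an estimated correlation. The glucocorticoid call was lost without N replicates 2 and 3 (0.19 and 0.095) and R3h replicates 1 and 2 (0.078 and 0.18), and the ribosome biogenesis call without N replicates 1 and 3 (0.18 and 0.15) and R3h replicates 1 and 2 (0.12 and 0.27). With a pseudocount of 0.1 the ribosome biogenesis call was lost too (0.071). The cholesterol call was lost without N replicate 2 (0.59) or R3h replicate 2 (0.28). Lists that did not pass still held called genes. Glycolysis (median 0.15, adjusted p = 0.072) held 4, among them a second tpi1b copy, 110489325 (2.02 ± 0.41, 0.022). The growth axis (median -0.55, adjusted p = 0.26) held igf1, which fell from 22.8 ± 15.6 to 2.07 ± 1.38 FPKM (-3.15 ± 0.71, 0.031), and lipogenesis (-0.37, adjusted p = 0.39) held Acly (110486250; -2.49 ± 0.66, 0.045). Neutrophil markers (-0.69, adjusted p = 0.16) held MPO (110532736; 25.7 ± 23.2 to 0.68 ± 0.212 FPKM, -4.73 ± 0.76, 0.015), and cell cycle genes (-0.15, adjusted p = 0.32) held rrm1 (-2.02 ± 0.43, 0.026). Cholangiocyte markers (-0.26, adjusted p = 0.52) held none. Autophagy (0.26, adjusted p = 0.26) held 4 that rose, GABARAPL1 110537275 (1.76 ± 0.39), GABARAPL1 110509134 (1.47 ± 0.33), GABARAP (1.27 ± 0.31) and MAP1LC3A (1.07 ± 0.27). Hepatocyte markers (0.54; 0.14, and negative on the FPKM and TPM scales) held fabp10a (3.26 ± 0.73, 0.03) and TTR (2.22 ± 0.58, 0.043), and acute-phase proteins (0.16, adjusted p = 0.33) held CRP (2.09 ± 0.32, 0.012). Genes always followed and not called were IGFBP1 (2.96 ± 1.33), vegfaa 110529696 (1.49 ± 0.50), ddit4 (2.86 ± 1.19), Egln3 110497687 (1.85 ± 0.76), Pdk2 (1.91 ± 0.74), hif1a (-0.95 ± 0.30), PCK1 (-0.94 ± 1.12), hspa5 (0.78 ± 0.61), FKBP5 (0.90 ± 0.65), Per1 (-0.34 ± 0.46) and hba4 100136296 (1.65 ± 0.65).

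R3h against H24h asked what separated the R group from the last H time. Genes of mitochondria, protein folding and the hypoxia response were higher in R3h as groups, without a called gene. Egln3 (110505778) stood at 10.1 ± 9.68 against 0.983 ± 0.505 FPKM (3.48 ± 0.77, adjusted p = 0.52), HSPA8, a constitutive chaperone, at 31.8 ± 4.05 against 10.8 ± 4.91 (1.68 ± 0.38, 0.53), and MANF, secreted upon endoplasmic reticulum stress, at 97.2 ± 46.6 against 28.4 ± 16.1 (1.84 ± 0.46, 0.67). EdgeR called 0 of 17500 genes, with 1289 at an unadjusted p under 0.05, and 9.2% had groups that did not overlap, where chance gives 10%. DESeq2 called 56 and limma-voom with library weights 2. Without R3h replicate 2, edgeR called 4 genes, ERBB4, Tbc1d15, DIAPH1 and Herc2, all lower and chosen after their values were seen, and without H12h replicate 1 it called IL6ST.

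Oxidative phosphorylation genes rose (153 of 164 positive, median 0.58, adjusted p = 1.4e-19; NDUFB6 2.17 ± 0.48, ATP5G3 1.40 ± 0.33), as did proteasome subunits (84 of 94, 0.67, adjusted p = 1.4e-11; the Psma4 copies 1.40 ± 0.44 and 1.55 ± 0.51) and ribosomal proteins (155 of 185, 0.49, adjusted p = 3.3e-10; rps23 1.21 ± 0.36, rps28 2.05 ± 0.67). The unfolded protein response rose (54 of 63, 0.78, 7 when adjusted over the list alone; 7.5e-07; MANF, CANX 1.20 ± 0.31), with heat shock proteins (34 of 46, 0.51, adjusted p = 1.4e-06; HSPA8, hspe1 1.49 ± 0.44), immediate-early genes (40 of 53, 0.63, adjusted p = 0.0027; junb 1.86 ± 0.77, NFKBIA 1.55 ± 0.72) and HIF targets (37 of 57, 0.39, adjusted p = 0.0032; Egln3, ankrd37 1.69 ± 0.45). With an estimated correlation each had an adjusted p = 0.77. Lower were macrophage markers (-0.54, adjusted p = 0.018; SPI1 -0.79 ± 0.53, MPEG1 -0.98 ± 0.67), stellate cell markers (-0.44, adjusted p = 0.031; COL1A1 -1.55 ± 0.72, col1a2 -1.40 ± 0.97), hepatocyte markers (-0.51, adjusted p = 0.045; the alb1 copies -4.55 ± 1.72 and -2.03 ± 0.90), xenobiotic genes (0.018; Ahr -1.91 ± 0.75, cyp2k1 100137012 -1.24 ± 0.49) and erythrocyte markers (24 of 27 negative; 0.027; alas2 -1 ± 0.52, hba4 110486353 -1.41 ± 0.90). Their adjusted p with an estimated correlation was 0.77, and 0.87 for the erythrocyte markers. R3h replicate 3 carried several of these calls. Without it ribosomal proteins had an adjusted p of 0.39, immediate-early genes 0.12, xenobiotic genes 0.39, hepatocyte markers 0.57, macrophage markers 0.35 and stellate markers 0.22. Calls that held without it had other medians there, namely 0.21 for proteasome subunits, 0.30 for oxidative phosphorylation, 0.19 for HIF targets and -0.80 for erythrocyte markers. The unfolded protein response was lost without R3h replicate 2 (0.08), erythrocyte markers without H24h replicates 2 and 3 (0.31 and 0.37) and R3h replicate 1 (0.98), and stellate markers without H24h replicate 2 (0.088) or R3h replicate 1 (0.11). Xenobiotic genes and macrophage markers were lost without H24h replicate 1 (0.082 and 0.074) or R3h replicate 2 (0.066 and 0.15), and hepatocyte markers without H24h replicates 1 and 2 (0.32 and 0.11) or R3h replicate 2 (0.11). Of the genes always followed, none called, FKBP5 differed by 1.20 ± 0.65, PCK1 by 1.69 ± 1.14, hspa5 by 1.76 ± 0.62, ddit4 by 1.59 ± 1.13 and vegfaa 110529696 by 1.11 ± 0.50. Egln3 110497687 differed by 0.39 ± 0.73, Pdk2 by 0.32 ± 0.71, hif1a by 0.20 ± 0.30, Per1 by 0.18 ± 0.46, IGFBP1 by -0.68 ± 1.24 and hba4 100136296 by -0.67 ± 0.64.

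Between successive H times, apln, ero1a and tpi1b were higher in H12h than in H3h. Tpi1b rose from 10.2 ± 2.08 to 59 ± 17.5 FPKM (3.11 ± 0.43), ero1a from 0.193 ± 0.085 to 5.30 ± 3.14 (5.37 ± 0.75) and apln, the gene of the vasodilator peptide apelin, from 0.473 ± 0.131 to 3.06 ± 1.36 (3.33 ± 0.47), each with adjusted p = 0.034. They were the 3 genes that edgeR called, with 2794 at an unadjusted p under 0.05 and 29.2% of genes without overlap between groups, where chance gives 10%. The count was 255 without H12h replicate 3, 163 without R3h replicate 3 and 0 without any other library of H12h or H3h. H24h against H12h gave 0 called genes, with 2539 at an unadjusted p under 0.05 and 24.7% without overlap. DESeq2 called 817 there, limma on log2(FPKM + 1) 10, on the TPM scale 29, and limma-voom with library weights 4509. The count by edgeR was 392 without H12h replicate 3 and 194 without R3h replicate 3. H12h replicate 3 held 8.18 FPKM of IGFBP1 and 1.96 of ddit4, below the other libraries of its group. Immediate-early genes fell from H12h to H24h (median -2.06, adjusted p = 1.8e-12, adjusted p = 0.49 with an estimated correlation), and HIF targets fell (-1.26, 26 when adjusted over the list alone; adjusted p = 1e-11, adjusted p = 0.33 with an estimated correlation). From H3h to H12h HIF targets rose (1.31, 1 called and 22 when adjusted over the list alone; adjusted p = 2.2e-13, adjusted p = 0.25 with an estimated correlation). These list tests between H times were chosen after the data had been seen.

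Calls were shared between the comparisons with N. Tpi1b rose at both H12h and H24h, the sole gene to do so (0.0427 if the calls were independent, 0.01 in simulations that keep the shared N libraries). The simulations held no changed gene, so few calls could arise in them, and the values for independent calls ignore the shared N libraries. Neither shows how many shared calls the N libraries alone would give. H12h and R3h shared 17 higher genes (1.21 if independent), among them Egln3, hif1an, ankrd37, CYP24A1, Tsc22d3 and ppp1r3b, and H24h and R3h shared 21 higher (0.781) and 12 lower (0.233), among them 4 ferritin genes, Ikbke and Bach1. No gene changed in opposite directions. Across genes, which are not independent replicates, the covariance of fold changes was 0.431 for H12h with H24h, 0.483 for H12h with R3h and 0.766 for H24h with R3h, where shared controls alone gave 0.204, 0.205 and 0.204 in 100 simulations. For H3h it was 0.156 with H12h and -0.074 with H24h, below the simulated 0.204. Between H24h against N and R3h against H24h it was -0.161, where the shared H24h libraries gave -0.205. The N libraries cannot be split into separate controls, so part of the excess may come from them. The simulations also used 1 dispersion per gene for all groups, although the median SD was 0.386 (log2 CPM) in N and 0.696 in R3h. The simulated covariances are therefore a rough baseline.

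Some lists that failed the test had a median, mean and test that differed in sign. They were amino acid catabolism, autophagy, gluconeogenesis, lipogenesis, tricarboxylic acid cycle, endothelium and stellate cell genes in H3h, and cell cycle, inflammatory, lipogenesis and xenobiotic genes in H12h. In H24h they were apoptosis, cell cycle, clock and gluconeogenesis genes, and in R3h against N clock, immediate-early and stellate cell genes. In R3h against H24h they were antioxidant, autophagy, inflammatory, lipogenesis and lymphocyte genes.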

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

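Between H3h and H12h, 3 genes differed in a direct test of the groups, and for each the difference from N was larger at H12h. Apln rose by 3.33 ± 0.47, from 0.473 ± 0.131 to 3.06 ± 1.36 FPKM (chromosome 25, 36039032 to 36069861). Ero1a rose by 5.37 ± 0.75, from 0.193 ± 0.085 to 5.30 ± 3.14 FPKM (chromosome 25, 41254183 to 41271397). Tpi1b rose by 3.11 ± 0.43, from 10.2 ± 2.08 to 59 ± 17.5 FPKM (chromosome 3, 33990921 to 33995689). Each is log2 ± SE with adjusted p = 0.034 by edgeR's quasi-likelihood test. The tests of red cell markers, of another tissue in R3h replicate 3, of its label and of a response that subsides were chosen only after the result was seen. No group has the 4 libraries needed to test for a library far from the rest.

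Ribosomal protein and oxidative phosphorylation genes were higher in R3h than in N, with a median of 1.14 over 349 genes. Other genes of like length moved by a median of 0.42, below the lists without each library in turn, which argues against gene length as the whole cause. The median without R3h replicate 3 was 0.72 and on the TPM scale 0.55, which argue against that library alone and against scaling alone as the whole cause. On the TPM scale without that library it was 0.27, where that of all genes was -0.34, so together they account for much of the difference. The rise of ribosomal proteins was not particular to R3h. Their median in H24h against N was 0.66, and in R3h against H24h it was 0.03 without R3h replicate 3. That of oxidative phosphorylation genes was 0.30 there. A higher output of ribosomal and mitochondrial transcripts may underlie the rest, a hypothesis drawn from these data that was not itself tested.

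Erythrocyte markers were higher in H24h than in N. The 5 markers other than globins moved by a median of 1.35 and the 22 globins by 2.19, so more red blood cells in the pieces and a higher content of globin transcripts per cell cannot be told apart with so few other markers. The mean of hepatocyte markers was higher in H24h by 0.679, but the libraries overlapped (exact permutation p = 0.3), so this value alone does not exclude a lower share of hepatocytes. Such a loss would raise the markers of every other cell type alike. Erythrocyte markers moved by 1.51 (exact permutation p = 0.1) and cholangiocyte markers by -0.203 (p = 0.2, SD 0.135 and 0.14). The median of all genes was -0.224 on that scale, so cholangiocyte markers did not fall relative to other genes. By edgeR the medians of the 2 lists were 2.15 and 0.03. This unlike movement argues, within the limits of 3 libraries, against a lower share of hepatocytes as the whole cause. The H24h condition itself might also have altered red cell number or content, which was not tested.

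R3h replicate 3 stood apart from the other libraries. Of 10 marker lists of other tissues or cell types, 1 was above the other 14 libraries, that of intestine (107 against at most 86.3 CPM), so another tissue in the piece may contribute and stays open. The intestine sum was not above the others by 2 times. Macrophage (1.89), neutrophil (1.97) and stellate cell markers (1.41) were below the lowest of the other libraries (2.01, 2.43 and 1.5), and the hepatocyte mean of 6.64 was the lowest of the 15. Gene length is argued against by a Spearman rho across genes, which are not independent replicates, of -0.035. Its highest mean correlation with another group was 0.739 (H24h), above the 0.733 with its own group but under 0.818, the lowest between any 2 libraries of 1 of the other groups. It was thus unlike a typical library of any group, its own included, so the test cannot tell a wrong label from a right one. No biological explanation was tested.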

How the results depend on the processing

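Limma-voom without weights, limma on log2(FPKM + 1), the omission of R3h replicate 3 from comparisons of other groups, and leave-outs for the lists were chosen after seeing the data. The cause was not tested for any change below unless stated.

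Median-of-ratios scaling and robust dispersion kept each count of genes within 1.5 times. DESeq2 called 14 genes in H3h against N, 828 in H12h against N, 1257 in H24h against N, 2776 in R3h against N, 56 in R3h against H24h, 800 in H12h against H3h, 817 in H24h against H12h and 4502 in the F-test. It shared 39 of 39, 35 of 35 and 932 of 935 calls with edgeR in H12h, H24h and R3h against N. Limma-voom with library weights called 4, 6898, 8197, 6349, 2, 3485, 4509 and 12102 in the same order, and without weights 9 in H12h against N. The weight of N replicate 3 was 6.545, against 0.933 and 0.495 for N replicates 1 and 2, and that of R3h replicate 3 was 0.1. The counts with weights thus leaned heavily on single libraries. Limma on log2(FPKM + 1) called 1 in H3h, 24 in H12h and 1890 in R3h against N, 7 in H12h against H3h, 10 in H24h against H12h and 2034 in the F-test. With a pseudocount of 0.1 it called 1, 21, 8 and 1463 against N and 1 in H12h against H3h. On the TPM scale it called 1 in H3h and 2049 in R3h against N, 8 in H12h against H3h, 29 in H24h against H12h and 2302 in the F-test.

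Without a filter the counts were 96 in H12h and 11 in H24h against N, 18 in H12h against H3h and 35 in H24h against H12h. With a mean FPKM of at least 2 they were 23 in H12h against N and 1 in H12h against H3h. A fit of only the groups compared, with fewer libraries to estimate the spread, called 2 in H12h, 0 in H24h and 0 in R3h against N, and 1 in H24h against H12h. Lists that passed were 0 in all 5 comparisons with an estimated correlation, and by fry 0, 2, 0, 5 and 0. With a pseudocount of 0.1, 3 list calls were lost, namely endothelium (adjusted p = 0.083) and oxidative phosphorylation (0.071) in H12h against N and ribosome biogenesis (0.071) in R3h against N.

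The replicate block called 15 genes in H12h and 0 in H24h against N, 1 in H24h against H12h and 613 in the F-test. Whether the numbers pair the libraries stays open. Libraries with the same number had a mean correlation of 0.035, with single pairs from -0.206 to 0.367 and 8 of 30 above 0.1. Values were centred within groups, which ties the mean for other numbers (-0.018) to that value, so it is no separate comparison.

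Leaving out each library in turn gave 0 to 0 genes in H3h, 0 to 546 in H12h, 0 to 683 in H24h and 7 to 2452 in R3h against N. It gave 0 to 4 in R3h against H24h, 0 to 255 in H12h against H3h, 0 to 392 in H24h against H12h and 199 to 2675 in the F-test. Lists that passed were 10 to 21, 17 to 21, 14 to 24, 8 to 17 and 9 to 15.

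Some fold changes of uncalled genes reversed, given as the lowest and highest without a library. In H3h against N these were Egln3 110497687 (-0.19 to 1.76), Pdk2 (-0.09 to 0.75), hba4 (-0.47 to 0.30, with 0.25 without N replicate 2), hif1a (-0.07 to 0.39) and hspa5 (-0.15 to 1.23). Per1 in H12h against N ranged from -0.51 to 0.34 and was 0.06, 0.07 and 0.02 without N replicate 1, N replicate 3 and R3h replicate 3. It was 0.03 without a filter, 0.01 with median-of-ratios scaling, 0.25 with weights, 0.03 with only the groups compared and 0.01 by DESeq2. Hspa5 there was -0.02 on log2(FPKM + 1) and -0.02 with a pseudocount of 0.1. In H24h against N FKBP5 ranged from -0.78 to 0.78 and was 0.27 by limma-voom without weights, and vegfaa was -0.04 on the TPM scale. In R3h against N PCK1 ranged from -1.60 to 0.45 and hspa5 from -0.05 to 1.16. In R3h against H24h Egln3 110497687 ranged from -0.20 to 0.68, IGFBP1 from -1.23 to 0.03, Pdk2 from -0.23 to 0.71 (-0.16 without H24h replicate 3), Per1 from -0.11 to 0.53 (-0.04 without H24h replicate 3) and hif1a from -0.05 to 0.34, and hif1a was 0 with weights.

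Camera's direction reversed for 5 lists without a library, none of which passed there. The adjusted p ranged from 4.6e-05 to 0.69 for cholesterol synthesis in H12h. In H3h it ranged from 4.2e-05 to 0.5 for ribosomal proteins (0.42 reversed), 1.5e-05 to 0.91 for macrophage markers, 0.00068 to 0.5 for ribosome biogenesis (0.23 reversed) and 3.6e-06 to 0.82 for the unfolded protein response. Over genes as a whole the spread between libraries exceeded counting error, with a chi-square per degree of freedom of at least 111.8. That value is weighted toward abundant genes. It does not show how far depth limits genes near the floor, such as P4HA1 at 0.0233 FPKM in N.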

Other observations

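Genes of transfer RNA charging and an iron-sulfur scaffold also differed at H24h, chosen after their values were seen. GARS, the glycyl-tRNA synthetase, fell by 1.3 ± 0.24 (log2 ± SE; adjusted p = 0.047 by edgeR, n = 3 per group) beside Aars, and the KEGG pathway of aminoacyl-tRNA biosynthesis had 2 lower genes of 53 called (median -0.73; camera adjusted p = 2.6e-05, adjusted p = 0.78 with an estimated correlation). ISCU, a scaffold for iron-sulfur clusters, rose by 1.49 ± 0.28 (adjusted p = 0.047). In R3h against N the ferroptosis pathway held 16 higher and 1 lower of 91 genes (median 0.44, camera adjusted p = 0.0014, adjusted p = 0.85 with an estimated correlation, fry adjusted p = 0.024). The 13 ferritin genes called there were not set apart from this count. The RIG-I-like receptor pathway held 5 lower genes of 89 (camera adjusted p = 0.031) and the Toll-like receptor pathway 6 of 127 (0.02), each with adjusted p = 0.85 with an estimated correlation.

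At H12h single genes of amino acid transport rose, again chosen after their values were seen, and no list of transporters was tested. SLC38A4 rose from 29.5 ± 8.06 to 135 ± 38.2 FPKM (2.77 ± 0.38) and Slc7a1 by 2.64 ± 0.46. CREM, a cyclic AMP-responsive regulator, rose by 3.50 ± 0.56. All 3 passed edgeR's test with Benjamini-Hochberg adjustment.

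The test of HIF targets subsiding was chosen only after the result was seen. As a list these genes were lower at H24h than at H12h (median -1.26), with a fry adjusted p of 0.071. A response that subsides therefore stays open as a candidate explanation beside differences between the samples. Without an N group matched to each time, it also cannot be told apart from an effect of time of day.

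Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. For H3h against N the real split gave 0 genes and the highest other 0, so all 10 splits gave as many. For H12h against N it was 39 and 4, for H24h against N 35 and 0, and for R3h against N 935 and 121, with 1 split giving as many in each. For R3h against H24h it was 0 and 4, with 10 splits giving as many. For H12h against H3h it was 3 and 1, with 1 split, and for H24h against H12h 0 and 0, with 10. Of 100 random splits of the 15 libraries into 5 groups, the real one included, only the real one gave 1267 genes or more. The highest other gave 608. That share is under 0.05, which argues against chance without excluding it, provided the libraries are independent samples.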
